A study of Mus musculus with 61 samples.

How the data were processed

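Liver RNA of mice from the 8 founder strains of the Diversity Outbred population, an outbred mouse stock bred from 8 inbred strains, was profiled by RNA sequencing. All mice had been kept on a high-fat, high-sugar diet, per the labels. Per the labels' protocols, total RNA was extracted from frozen, pulverised tissue, external RNA controls were added, and libraries were made from polyadenylated RNA. The external controls were not used here. The labels name 61 samples, each with a strain and a number. The count table held a column for 60 of them, 129 (n = 8), AJ (n = 6), B6 (n = 7), Cast (n = 7), NOD (n = 8), NZO (n = 8), PWK (n = 8) and WSB (n = 8), and these 60 libraries entered every fit. The strain labelled 129 is written strain-129 in the results, so that its name is not read as a number. The sample numbered 5 of B6 had no column, and 1 column whose name matched no sample was not used. The labels give no sex, age or collection time, and they do not state in so many words that each library is from a separate mouse. The p-values therefore measure the spread between these libraries, which may be partly technical. Each strain also held libraries of high and of low Xist, the RNA of the inactive X chromosome, which the main model pooled. Differences between the high- and low-Xist libraries are thus part of that spread.

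The authors deposited estimated counts of reads per gene, not normalised, of which 21% of the values were not whole numbers. The design had assumed whole counts, so the estimated counts were rounded to whole numbers before testing. The authors also deposited log2-scale values from a variance-stabilising transformation, which served as an alternative. Per the submitters' processing notes, the genome build was GRCm38 and DESeq2 was used, without a version. The aligner, the counting tool, the annotation release and whether counting used strand are not given in the sources used here. Reads of near-identical genes (major urinary proteins, alpha globins, histone, cytochrome P450, glutathione transferase, Serpina1 and MHC families) and of overlapping or antisense genes could have been split in ways that cannot be told from the counts, so values of such genes are uncertain. Gene positions are those of the deposited gene table, per the file headers, in GRCm38. The tables held 18754 genes, each above 0 in at least 29 of the 60 libraries, so a gene seen in a single strain could be absent from them. Of these, 18684 had their identifier in the reference annotation used here, and 40 had a symbol used more than once.

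Totals ranged from 19.98 to 69.17 M reads per library, with a median of 30.42 M. A gene at 1 CPM (counts-per-million) was covered by 1 read for each M reads of its library. Reads are not independent molecules where polymerase chain reaction copies them, so read numbers describe counting error alone. Where a strain had 3 reads or fewer of a gene, levels are given and no fold change.

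Counts were analysed in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM normalisation, filterByExpr by strain), which left 16165 genes. A single model with strain as the only factor gave the test among the 8 strains and the contrasts between pairs of strains. It also gave the contrast of each strain with the unweighted mean of the other 7. This mean was taken on the log scale, so a strain near 0 lowers it and raises the fold changes of the others. For Mx2, with NZO at 0.0193 CPM, NOD had a log2 fold change of 0.02 at 5.15 CPM. Cast was at 73.9 CPM and PWK at 63.2 CPM. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. A gene that passed is described as called. Fold changes are log2 values and refer to the mean of the other 7 strains unless a pair is named. The standard error (SE) given with them is the absolute fold change divided by the square root of the F statistic. It was not taken from the fit and can mislead where a strain is near 0 reads. For Mx2, with NZO at 0.0193 CPM, it was 0.12 in NOD (5.15 CPM) and 0.50 in WSB (4.76 CPM). Levels are mean CPM ± SD over the libraries of a strain. Variance shares and principal components used log2 CPM with a prior count of 2.

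The tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule named, for each strain, the 5 called genes with the largest positive and the 5 with the largest negative fold change among protein-coding genes with a mean of at least 5 CPM, leaving out predicted genes, olfactory receptors, Xist and Y-linked genes. It also named up to 4 members of each list called by camera in that strain, chosen by smallest p in the direction of the list, and each gene of a set of core liver genes that was called with a log2 fold change of at least 1 in either direction. Genes with known differences between mouse strains were named with their level in every strain. Some genes that the rule named are not reported here and were left out of the comparison of single libraries, while counts of genes and lists include them. Other genes in the text, including further members of lists, were chosen after their values were seen.

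The 35 gene lists covered lipid, glucose, bile acid and amino acid metabolism, drug metabolism, sex-biased genes, immune and stress responses, the clock, the cell cycle, and markers of the other cell types a liver sample can hold. The 33 with at least 5 tested members gave 264 tests of a list in a strain. Camera in limma 3.58.1, with a preset correlation between genes of 0.01, was the planned list test, adjusted over all 264. The apolipoprotein list has 22 symbols but 23 tested genes, since Apoc2 stands for 2 identifiers. After the data had been seen, a list score was added. It is the mean log2 CPM of a list's members in each library, compared between a strain and all other libraries by a two-sided permutation test of the strain labels (100000 permutations, smallest possible p 1e-05), adjusted over the same 264 tests. The smallest p that the permutations can give corresponds to an adjusted p of 0.000293. Counts of members are also given adjusted over the list alone.

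The edgeR steps were tested on simulated counts drawn from the means and library sizes of these data, for the contrast of AJ with the other 7 strains and 16165 genes. Of the genes changed 1.5-fold, 67.16% of 67 were recovered, of those changed 2-fold, 89.55% of 67, and of those changed 4-fold, 95.45% of 66. Of 15965 unchanged genes, 9 were called. No contrast without a simulated change gave more than 3 calls. Apart from the changes in AJ, each simulated gene had the same mean in every strain, and genes were drawn independently of one another. The simulation therefore checks the steps and does not give the rate of false calls in these data.

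Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, a filter at a mean of 1 CPM, limma-voom, limma on the deposited log2-scale values, the sample number as a block, the log2 CPM of Xist as a covariate, a library number from the sample titles as a covariate, and, for the lists, an estimated correlation. Leaving out each of the 60 libraries in turn was added after the data had been seen, because NZO 8 and Cast 5 stood apart, as was a red cell score without the alpha globins. The strain labels were permuted 39 times to give 40 splits with the real one, a number set by computing time. No fold change, level or list was compared with a control diet, since all libraries are from mice on the same diet.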

Results

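Liver gene expression was compared among the 8 founder strains of the Diversity Outbred stock, all kept on a high-fat, high-sugar diet, in 60 RNA sequencing libraries. Depth per library ranged from 23.3 to 40.3 M reads in strain-129 (n = 8), from 27.4 to 41.5 M in AJ (n = 6), from 19.98 to 38.2 M in B6 (n = 7), from 26.7 to 38.2 M in Cast (n = 7), from 22.97 to 34.3 M in NOD (n = 8), from 22.4 to 69.2 M in NZO (n = 8), from 25.1 to 36.6 M in PWK (n = 8) and from 21.9 to 44.9 M in WSB (n = 8). Between 16964 and 18378 of the 18754 genes were above 0 in a library, and mitochondrial genes took 4.61 to 9.23% of its reads. Rn18s-rs5, an 18S ribosomal RNA sequence, was the gene with the most reads in many libraries. Its share was 16.0% in NZO 4, 15.9% in NZO 3, 13.8% in NZO 7 and 11.3% in NZO 6. It was 7.23% in NZO 8 and 9.48% in NOD 6, and in NZO 2 Alb had the most reads. Every library correlated best with another of its own strain across genes (Pearson's r of 0.948 to 0.990, over genes, which are not independent replicates). No pair of libraries of a strain was alike within sampling noise, since the lowest chi-square per gene was 15.9.

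Most liver genes differed among the strains, 14518 (89.81%) of 16165 tested. The share of a gene's variance of log2 CPM that lay between strains had a median of 49.28% over genes. In 100 permutations of the strain labels it was typically 10.78% (the median) and at most 13.85%. The first 3 principal components held 21.3%, 12.74% and 10.59% of the variance. Cast, a strain derived from wild mice, had the most called genes against the mean of the other 7 strains, 9630 (59.57%), followed by NZO (7455), PWK (7302), WSB (7277), B6 (5506), NOD (4580), strain-129 (3979) and AJ (3893). Among pairs of strains, strain-129 and AJ differed in the fewest genes (2327) and Cast and NZO in the most (9531). Pairs of strain-129, AJ and NOD differed in at most 2614 genes, and NZO differed in fewer genes from B6 (3543) than from any other strain. The contrasts below ask which genes and gene groups set each strain apart on this diet. A gene given with an adjusted p lay on the stated side of the mean of the other strains in every library of its strain, unless another number is given. Values of a gene without a unit are log2 fold changes, with the SE after the sign ±.

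**Figure D1:**
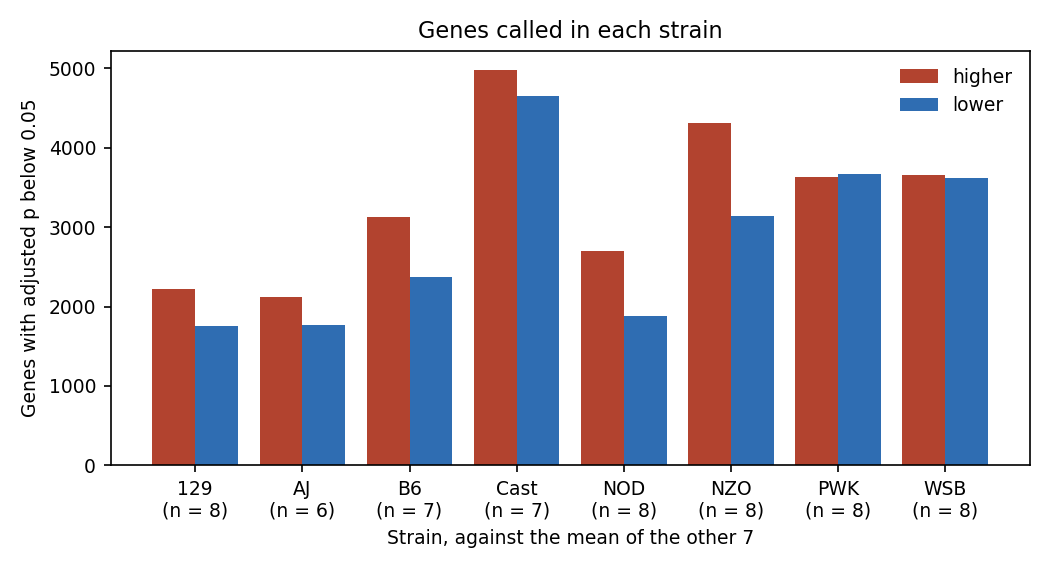
Bars give the number of genes called in each strain against the mean of the other 7 strains (edgeR, adjusted p under 0.05), with higher and lower genes apart and the number of libraries under each strain. Cast has the most on both sides, 4974 higher and 4656 lower.

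**Figure D2:**
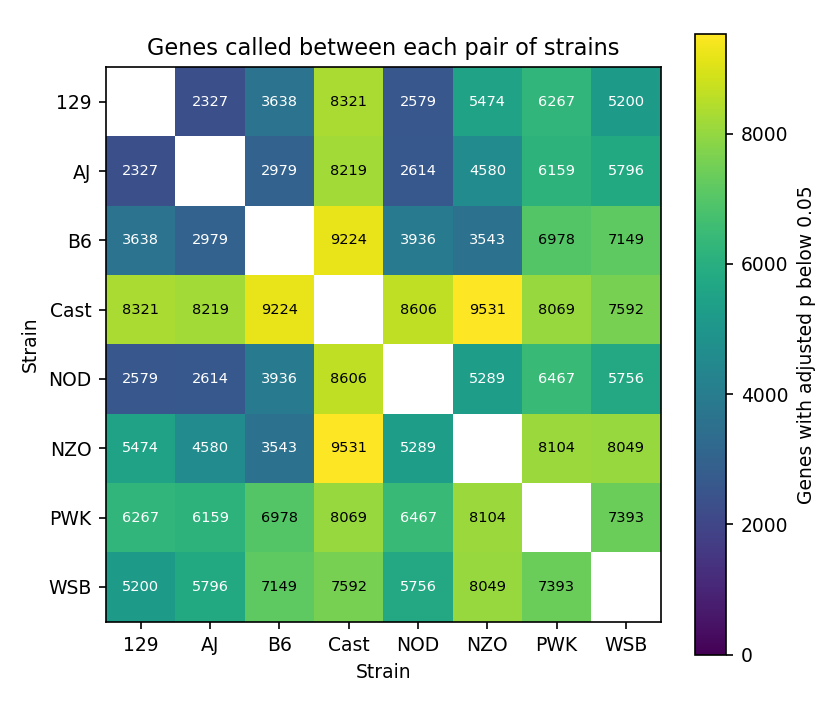
Each cell of the matrix gives the number of genes called between a pair of strains, from 2327 between strain-129 and AJ to 9531 between Cast and NZO.

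Gene lists were compared by the number of called members and by the list score, the mean log2 CPM of the members in a library. The score of a strain differed from that of all other libraries in 49 of 264 tests (permutation adjusted p), of which 34 were also called by camera. Camera called 58, and none of them was called with an estimated correlation, where the lowest adjusted p was 0.9995 and 8 tests had an unadjusted p under 0.05. In 38 of 40 splits of the libraries, the real one included, camera called at least as many lists, so counts and scores lead here. A count of called members is to be read beside the share of all genes called in that strain. This share was 24.61% in strain-129, 24.08% in AJ, 34.06% in B6 and 59.57% in Cast. In NOD it was 28.33%, in NZO 46.12%, in PWK 45.17% and in WSB 45.02%. A count near the share of its strain says nothing particular about the list. Of the 58 camera calls, 19 ended without at least 1 of the 60 libraries. These were cholesterol synthesis in strain-129, fatty acid synthesis, female-biased, class II and immediate early genes in AJ, and cholesterol synthesis, lipid droplet, class II and stellate genes in B6. They were also conjugation and Kupffer genes in Cast, interferon, class II and oxidative phosphorylation genes in NOD, P450, class I, urea cycle and neutrophil genes in NZO, and NRF2 targets in PWK. The P450 call in NZO ended in 47 of the 60 leave-outs, the immediate early call in AJ in 42, and each of the others in at most 9. Cast had the most score calls, 15, followed by NZO with 11, while strain-129 had 0 score calls.

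**Figure D3:**
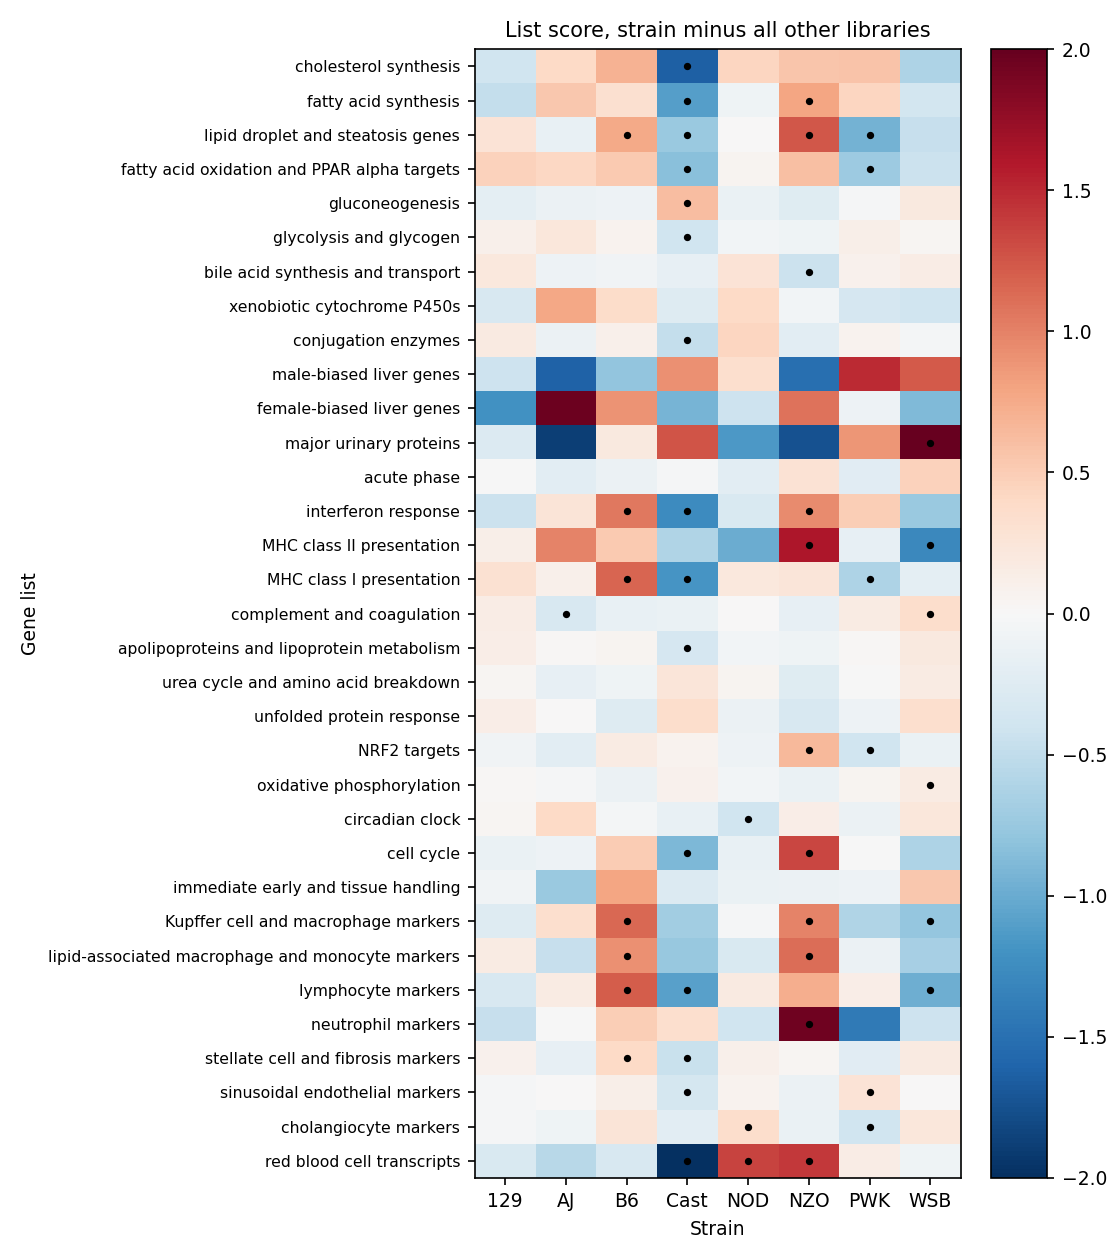
The heatmap shows the list score of each strain minus that of all other libraries on the log2 scale (colours from -2 to 2) for 33 lists and 8 strains, and a black dot marks a permutation adjusted p under 0.05. Interferon response genes, for example, are higher in B6 (1.06) and NZO (0.95) and lower in Cast (-1.26).

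In strain-129, 14 of 35 fatty acid oxidation genes were higher and 16 of 41 interferon response genes lower (7 without library 3 of strain-129 and 9 without its library 8), but the score of neither list was called (permutation adjusted p = 0.227 and 0.361). Acadm, the medium-chain acyl-CoA dehydrogenase, was higher by a log2 fold change of 0.85 ± 0.12 (SE, adjusted p = 3.79e-08) at 502 ± 56.0 CPM (SD, n = 8). Fgf21, a liver hormone induced by fasting and by PPAR alpha, was higher by 1.66 ± 0.36 (adjusted p = 0.000305). Apoa4, an apolipoprotein, was at 3200 ± 623 CPM against 608 CPM in AJ to 1680 CPM in Cast. The protease cathepsin E (Ctse, ENSMUSG00000004552, chromosome 1, 131638306 to 131675505) was higher by a log2 fold change of 5.46 ± 0.21 (adjusted p = 1.56e-29) at 80.5 ± 22.7 CPM, against 0.266 to 34.9 CPM in the other strains. Sult1e1, the estrogen sulfotransferase (ENSMUSG00000029272, chromosome 5, 87575969 to 87591594), was higher by 4.60 ± 0.29 (adjusted p = 2.5e-19), as were Fam213b (2.79 ± 0.15) and the drug transporter gene Abcb1b (2.65 ± 0.26). Cyp2b9, a P450 of a family with near-identical members, was lower (-8.06 ± 1.66, adjusted p = 0.000159) at 0.789 ± 0.915 CPM. Nlrp12, a receptor of the NLR family, was lower as well (-4.83 ± 0.62, adjusted p = 1e-08).

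The 3979 genes called in strain-129 comprised 2218 higher and 1761 lower. Of 35 fatty acid oxidation and PPAR alpha target genes, 14 were higher and 0 lower (20 and 1 adjusted over the list alone, and 7 higher without library 3 and 9 without library 4 or 9 of strain-129), among them Eci2 (0.55 ± 0.10) and Acadvl (0.23 ± 0.05). The interferon list had 2 higher and 16 lower of 41 (2 and 19 adjusted over the list alone), with 9 lower without library 8 and 10 without library 6. Bst2 was at -0.77 ± 0.13, Oasl1 at -1.50 ± 0.29 and Parp14 at -0.57 ± 0.13. Cholesterol synthesis had 0 higher and 5 lower of 22 (0 and 2 adjusted over the list alone), a count of 5 that moved by over 1.5 times in 12 of the 60 leave-outs, to 2 without library 3, 6, 8 or 9. The lower members included Hmgcs1 (-1.12 ± 0.29). Camera called these 3 lists, each with an adjusted p of 0.9995 with an estimated correlation. The permutation adjusted p of the cholesterol score was 0.451. With the log2 CPM of Xist as a covariate, camera also called fatty acid synthesis (adjusted p = 0.042) and the female-biased list (0.0324), each with an adjusted p of 0.9995 with an estimated correlation and no covariate. Pparg, a lipogenic regulator, was higher by 1.38 ± 0.26. The call of Lss ended in 13 of the 60 leave-outs (highest adjusted p = 0.126, without library 3), that of Cyp4a14 without libraries 1, 3 or 4 (at most 0.0837) and that of Pnpla3 without libraries 3, 7 or 8 (at most 0.0525), and Pnpla3, lower in 6 of 8 libraries, was at -2.11 ± 0.71 and at -2.84 without library 1.

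In AJ, the score of the complement and coagulation list was lower, while that of the interferon list was not called (permutation adjusted p = 0.643). The interferon list had 10 higher and 0 lower of 41 (also 10 and 0 adjusted over the list alone), with 3 higher without AJ 3 and 2 without AJ 4. Gbp6 (ENSMUSG00000079362, chromosome 5, 105214907 to 105293695) was at 34.8 ± 17.5 CPM (SD, n = 6) against 0.0109 CPM in Cast to 9.14 CPM in NZO. Gbp10 was higher by a log2 fold change of 3.27 ± 0.29 (SE, adjusted p = 8.09e-14). Both are guanylate-binding proteins. Apol9b (ENSMUSG00000068246, chromosome 15, 77729121 to 77736381) was higher by 3.46 ± 0.21 (adjusted p = 2.11e-20), with a mean of 67.1 CPM in AJ and in B6. Gvin1, a very large inducible GTPase (ENSMUSG00000045868, chromosome 7, 106156556 to 106215326), had 0 reads in AJ, where the other strains averaged 0.132 CPM (strain-129) to 46.1 CPM (B6). Nnmt, the nicotinamide methyltransferase, was lower by 4.54 ± 0.65 (adjusted p = 1.86e-07) at 2.51 ± 1.19 CPM.

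The 3893 genes called in AJ comprised 2121 higher and 1772 lower. Complement and coagulation had 6 higher and 5 lower of 27 (7 and 6 adjusted over the list alone, and 3 higher without AJ 1 or AJ 8), and its score was lower by 0.32 (permutation adjusted p = 0.0455). The median fold change of its members was 0.14 and the mean -0.38. The lower members included Hc, complement component C5 (-1.64 ± 0.16), and the coagulation factor gene F12 (-0.84 ± 0.10), while F5 was higher (0.38 ± 0.09). Of 22 fatty acid synthesis genes, 6 were higher and 0 lower (also 6 and 0 adjusted over the list alone, and 3 higher without AJ 3), among them Dgat2 (0.50 ± 0.12), the last enzyme of triglyceride synthesis, the regulator Srebf1 (0.83 ± 0.22) and Elovl5 (0.77 ± 0.23). MHC class II had 2 of 8 higher, H2-Ea-ps and H2-Eb1 (5 adjusted over the list alone), and the female-biased list 4 of 21 higher (also 4 adjusted over the list alone, and 2 without AJ 2 or AJ 4), Cyp2b13, Cyp2b9, Nipal1 and Atp6v0d2. Of 15 immediate early genes, 1 was lower, Hspa1a (-2.21 ± 0.62 and -3.09 without AJ 8, also 1 adjusted over the list alone), against 3 without AJ 4 and 2 without AJ 8. Camera called these last 4 lists, with an adjusted p of 0.9995 with an estimated correlation. The permutation adjusted p of their scores was 0.285, 0.0947, 0.384 and 0.108. With the log2 CPM of Xist as a covariate, the camera calls of fatty acid synthesis (adjusted p = 0.0549) and of the female-biased list (0.126) ended. AJ had 4 libraries with high and 2 with low Xist.

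Of 19 major urinary protein genes, a family of similar genes among which reads could be shared, 8 were lower in AJ (9 adjusted over the list alone, permutation adjusted p = 0.181). Mup17 was at -5.10 ± 1.26. The median of this list was -2.88, and -1.82 with the Xist covariate, where camera called it (adjusted p = 0.00609), against an adjusted p of 0.9995 with an estimated correlation and no covariate. Cyp4a14, a PPAR alpha target, was higher at 863 ± 291 CPM (2.35 ± 0.71), while Cidec (-2.56 ± 0.78) and Apoa4 (-1.35 ± 0.36) were lower. Calls of 8 named genes ended when single libraries were left out. Saa1 lost its call in 37 of the 60 leave-outs (highest adjusted p = 0.0973) and Moxd1 in 11 (0.134). Those of Pnpla3 (1.06, 0.255) and Mid1ip1 (0.0628) ended without AJ 3, Nipal1 without AJ 4 (0.0658), Cyp2b9 without AJ 2 (0.0502), and Atp6v0d2 without AJ 1, 2, 3 or 4 (at most 0.0691). That of Gvin1, with 0 reads in AJ, ended without library 1 of strain-129. A fold change has no defined value at 0 reads, so this ending says little about the level of Gvin1 in AJ.

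B6 had higher levels of interferon response, MHC class I and macrophage genes than the mean of the other strains. Of 41 interferon response genes, 34 were higher and 0 lower (also 34 and 0 adjusted over the list alone). Ifit3 was at 1.99 ± 0.21 (SE), Irf7, a master regulator of the response, at 1.51 ± 0.19 and Oas3 at 1.96 ± 0.25. The score was higher by 1.06 (permutation adjusted p = 0.00384). Of 18 Kupffer cell and macrophage markers, 15 were higher (also 15 adjusted over the list alone, score 1.15, permutation adjusted p = 0.0028). Folr2 was at 12.1 ± 4.07 CPM (SD, n = 7, log2 fold change 2.93 ± 0.17, adjusted p = 1.44e-21), and Csf1r, the receptor of a macrophage growth factor, at 99.1 ± 32.1 CPM (1.42 ± 0.17). MHC class I, a family of similar genes among which reads could be shared, had 16 higher and 2 lower of 19 (also 16 and 2 adjusted over the list alone, score 1.17, permutation adjusted p = 0.000293). H2-K1 was at 1040 ± 89.3 CPM and H2-D1 at 471 ± 48.1 CPM. Reads of other strains could have been lost at class I alleles that differ from the reference sequence, which was not tested.

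Lymphocyte markers had 18 higher of 22 (19 adjusted over the list alone, score 1.21, permutation adjusted p = 0.00132). The B cell gene Ighd was at 1.09 ± 0.322 CPM. Lipid-associated macrophage markers had 8 of 12 higher (also 8 adjusted over the list alone, 5 without B6 6, score 0.91, permutation adjusted p = 0.0245), including Itgax (2.22 ± 0.26) and Trem2 (2.24 ± 0.32). Stellate cell and fibrosis markers had 11 higher and 1 lower of 22 (13 and 1 adjusted over the list alone, score 0.40, permutation adjusted p = 0.00462), among them the collagen genes Col1a1 (1.54 ± 0.24) and Col3a1 (1.29 ± 0.23). Lipid droplet genes had 9 higher and 0 lower of 19 (10 and 0 adjusted over the list alone, score 0.76, permutation adjusted p = 0.0375). Pparg was at 2.60 ± 0.25, Fitm1 at 2.61 ± 0.40 and G0s2, an inhibitor of lipolysis, at 1.83 ± 0.30. Cholesterol synthesis had 14 higher of 22 (15 adjusted over the list alone), 6 without B6 6 and 9 without B6 8. Hmgcs1 was at 1.52 ± 0.24 and Sc5d at 1.09 ± 0.20. MHC class II had 6 higher and 1 lower of 8 (7 and 1 adjusted over the list alone). H2-Eb1 was at 2.10 ± 0.25. Oxidative phosphorylation had 0 higher and 13 lower of 39 (0 and 15 adjusted over the list alone). Atp5o was at -0.33 ± 0.06. The permutation adjusted p of these last 3 was 0.17, 0.424 and 0.209. In B6, camera called the interferon, Kupffer, class I, lymphocyte, lipid-associated macrophage, stellate, lipid droplet, cholesterol, class II and oxidative phosphorylation lists, with an adjusted p of 0.9995 with an estimated correlation.

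Raet1d, a ligand of an activating receptor of natural killer cells (ENSMUSG00000078452, chromosome 10, 22360552 to 22374139), was higher in B6 by 4.05 ± 0.22 (SE, adjusted p = 2.81e-22) at 18.9 ± 8.74 CPM (SD, n = 7). Ceacam2 (ENSMUSG00000054385, chromosome 7, 25516042 to 25539857) was lower by 4.30 ± 0.31 (adjusted p = 3.1e-17). Gvin1 was at 46.1 ± 25.1 CPM against at most 5.48 CPM elsewhere. Immediate early genes had 8 higher and 1 lower of 15 (10 and 2 adjusted over the list alone, permutation adjusted p = 0.0595), with 4 higher without B6 2. Cyp2c39, a P450 with near-identical relatives, was lower (-5.11 ± 1.14, adjusted p = 0.000342). In all, 3131 genes were higher and 2375 lower in B6. Mmp12 was higher by 2.13 ± 0.37 in 5 of 7 libraries and by 1.10 without B6 6, and without B6 3 the call of Cyp4a14 ended (adjusted p = 0.0969).

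Cast had lower levels of cholesterol synthesis, fatty acid synthesis and interferon genes, and higher levels of gluconeogenesis genes. Of 22 cholesterol synthesis genes, 20 were lower and 0 higher (also 20 and 0 adjusted over the list alone, score -1.63, permutation adjusted p = 0.000293). Pmvk was at -3.17 ± 0.34 (SE) and Insig1 at -1.95 ± 0.26. Fatty acid synthesis had 16 lower and 0 higher of 22 (16 and 1 adjusted over the list alone, score -1.10, permutation adjusted p = 0.00347). Fasn, the fatty acid synthase, was at 422 ± 200 CPM (SD, n = 7) against 531 to 2960 CPM and Srebf1 at -1.06 ± 0.24. Gluconeogenesis had 11 higher and 2 lower of 16 (also 11 and 2 adjusted over the list alone, score 0.62, permutation adjusted p = 0.00072). Ppargc1a, a fasting-induced coactivator, was at 1.80 ± 0.22, Pck1 at 0.75 ± 0.16 and G6pc at 0.58 ± 0.20, while Fbp1 was lower (-0.49 ± 0.14). Glycolysis and glycogen had 4 higher and 10 lower of 21 (also 4 and 10 adjusted over the list alone, score -0.40, permutation adjusted p = 0.00384). Pklr, the liver pyruvate kinase, was at -1.43 ± 0.30.

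Of the single genes, Eno1b, an enolase-like gene (ENSMUSG00000059040, chromosome 18, 48045335 to 48048378), was at 152 ± 22 CPM in Cast against at most 0.78 CPM elsewhere (8.62 ± 0.26, adjusted p = 3.55e-35). Its reads could be shared with other enolase genes. The beta-defensin Defb1 (ENSMUSG00000044748, chromosome 8, 21776599 to 21795185) was at 126 ± 132 CPM against at most 2.59 CPM (6.94 ± 0.23, adjusted p = 1.34e-32). Lepr, the leptin receptor, was at 417 ± 433 CPM against at most 32.6 CPM (4.45 ± 0.41, adjusted p = 5.32e-14), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 254 ± 179 CPM (2.20 ± 0.33, adjusted p = 7.13e-08). The immunity-related GTPase Iigp1 (ENSMUSG00000054072, chromosome 18, 60376029 to 60392627) was at 0.426 ± 0.400 CPM against 205 to 366 CPM (-9.38 ± 0.40, adjusted p = 4.85e-28). Rarres1 (ENSMUSG00000049404, chromosome 3, 67478972 to 67515523) was at 0.0626 ± 0.0504 CPM against 20.6 to 51.9 CPM. In all, 4974 genes were higher and 4656 lower, and of the 1115 called with at least a 4-fold difference 62.15% were lower.

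The interferon list had 2 higher and 32 lower of 41 in Cast (also 2 and 32 adjusted over the list alone, score -1.26, permutation adjusted p = 0.000293). Irf7 was at -2.34 ± 0.27 (SE) and Gbp7 at -2.50 ± 0.32. MHC class I had 16 lower of 19 (also 16 adjusted over the list alone, score -1.18, permutation adjusted p = 0.000293). H2-D1 was at -1.09 ± 0.11. Lymphocyte markers had 16 lower of 22 (also 16 adjusted over the list alone, score -1.09, permutation adjusted p = 0.00425). Ptprc, the CD45 gene, was at 5.90 ± 1.10 CPM. Sinusoidal endothelial markers had 2 higher and 9 lower of 16 (2 and 10 adjusted over the list alone, score -0.35, permutation adjusted p = 0.00072). Cdh5 was at -0.75 ± 0.09. Red cell transcripts had 7 lower of 8 (also 7 adjusted over the list alone, score -2.04, permutation adjusted p = 0.000293). Without the alpha globins Hba-a1 and Hba-a2, among which reads could be shared, this score was -1.63 (permutation adjusted p = 0.000377). Slc4a1 was at -3.11 ± 0.48. Stellate cell markers had 6 higher and 11 lower of 22 (also 6 and 11 adjusted over the list alone, 2 higher without Cast 6, score -0.44, permutation adjusted p = 0.00132). Col3a1 was at -1.80 ± 0.30 but Dcn at 0.33 ± 0.06. Cell cycle genes had 2 higher and 10 lower of 17 (also 2 and 10 adjusted over the list alone, 1 higher without Cast 5, score -0.90, permutation adjusted p = 0.0182). Mki67 was at -2.86 ± 0.42. Kupffer cell markers had 1 higher and 14 lower of 18 (also 1 and 14 adjusted over the list alone, permutation adjusted p = 0.0893). Folr2 was at -3.71 ± 0.30.

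Fatty acid oxidation had 3 higher and 19 lower of 35 in Cast (also 3 and 19 adjusted over the list alone, 0 higher without Cast 1, score -0.84, permutation adjusted p = 0.018). Hadh was at -1.19 ± 0.16 (SE) and Acads at -0.88 ± 0.11. Conjugation enzymes had 9 higher and 18 lower of 38 (also 9 and 18 adjusted over the list alone, score -0.47, permutation adjusted p = 0.0429). Gstt1 was at -4.12 ± 0.27. Lipid droplet genes had 4 higher and 8 lower of 19 (also 4 and 8 adjusted over the list alone, score -0.74, permutation adjusted p = 0.0432). Pparg was at -2.61 ± 0.41 and Plin2 at -0.92 ± 0.21. Apolipoproteins had 5 higher and 9 lower of 23 (also 5 and 9 adjusted over the list alone, score -0.34, permutation adjusted p = 0.00928). Apom was at -1.07 ± 0.17. Without Cast 5, the permutation adjusted p of these 4 scores was 0.0796, 0.18, 0.0998 and 0.0532. Camera called cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, conjugation enzymes, interferon, MHC class I, Kupffer, lymphocyte, endothelial and red cell lists, with an adjusted p of 0.9995 with an estimated correlation. Cyp2b10 was higher in 3 of 7 libraries and at 0.29 without Cast 1 (adjusted p = 0.81), and Cidec was at 1.90 without Cast 1. Saa1 was higher in 4 of 7 libraries, and its call ended without Cast 6 (1.59, adjusted p = 0.0734).

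NOD had higher red cell transcripts, while the scores of conjugation enzymes and MHC class II missed the threshold. Of 8 red cell transcripts, 6 were higher and 0 lower (8 and 0 adjusted over the list alone, score 1.35, permutation adjusted p = 0.00308). Alas2, the erythroid enzyme of heme synthesis, was at 2.27 ± 0.38 (SE) and the beta globin Hbb-bt at 1.39 ± 0.19. Hba-a1 was at 109 ± 27.4 CPM (SD, n = 8) but reads could be shared with Hba-a2, and the log2 ratio of their sum to Hbb-bs spanned 0.43 over the strains. Without both, the red cell score was 0.905 (permutation adjusted p = 0.0178). Camk2b, a calcium-dependent kinase (ENSMUSG00000057897, chromosome 11, 5969644 to 6066362), was higher by 5.49 ± 0.25 (adjusted p = 8.46e-26) at 37.0 ± 12.4 CPM. B4galnt1, an enzyme of ganglioside synthesis (ENSMUSG00000006731, chromosome 10, 127165156 to 127172340), was at 1.32 ± 0.849 CPM against 64.4 to 88.3 CPM in the other strains (-5.81 ± 0.22, adjusted p = 1.7e-29). Crym (ENSMUSG00000030905, chromosome 7, 120186380 to 120202111) was lower by 4.20 ± 0.23 (adjusted p = 1.83e-22).

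Of the 4580 genes called in NOD, 2700 were higher and 1880 lower. Conjugation enzymes had 13 higher and 1 lower of 38 (14 and 1 adjusted over the list alone), 4 of them glutathione transferases of the mu family, Gstm1, Gstm2, Gstm3 and Gstm6, among which reads could be shared. MHC class II had 6 lower of 8 (7 adjusted over the list alone). Cd74 was at -0.88 ± 0.26 and H2-Ab1 at -0.95 ± 0.27, each in 7 of 8 libraries. The scores of both lists had a permutation adjusted p of 0.0519, and without Cast 5 of 0.0483 and 0.039. Without NZO 8, that of the conjugation enzymes was 0.0306. Cholangiocyte markers had 3 higher and 0 lower of 9 (also 3 and 0 adjusted over the list alone, score 0.36, permutation adjusted p = 0.00556). Sox9 was at 1.83 ± 0.22 and Krt19 at 0.71 ± 0.18. Clock genes had 0 higher and 6 lower of 18 (1 and 6 adjusted over the list alone, score -0.40, permutation adjusted p = 0.0438). Dbp was at -3.96 ± 1.11 and Per3 at -1.95 ± 0.62. Interferon genes had 1 higher and 10 lower of 41 (1 and 14 adjusted over the list alone, 6 lower without NOD 8, permutation adjusted p = 0.565), and oxidative phosphorylation had 0 higher and 11 lower of 39 (0 and 12 adjusted over the list alone, permutation adjusted p = 0.534). Camera called the red cell, conjugation, class II, interferon and oxidative phosphorylation lists, with an adjusted p of 0.9995 with an estimated correlation. The leptin receptor gene Lepr was lower (-2.27 ± 0.62), and Cyp2b10 was higher in 6 of 8 libraries (3.62 ± 0.68, 2.66 without NOD 1).

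NZO had higher levels of lipid droplet, fatty acid synthesis, interferon and class II antigen presentation genes. Of 19 lipid droplet and steatosis genes, 15 were higher and 1 lower (also 15 and 1 adjusted over the list alone and without NZO 8, score 1.24, permutation adjusted p = 0.000293). Mogat1, a monoacylglycerol acyltransferase, was at 4.78 ± 0.33 (SE), Pparg at 2.65 ± 0.24 and Vldlr at 2.71 ± 0.39. Fatty acid synthesis had 13 higher and 1 lower of 22 (14 and 1 adjusted over the list alone, score 0.79, permutation adjusted p = 0.037). Elovl6 was at 2.09 ± 0.32, Acly at 1.71 ± 0.26 and Fasn at 1.83 ± 0.28 in 6 of 8 libraries. Scd1, the stearoyl-CoA desaturase, averaged 31400 ± 18100 CPM (SD, n = 8) against 4380 to 16900 CPM in the other strains, and Cd36, the fatty acid translocase, was higher by 1.80 ± 0.31. Cholesterol synthesis had 11 higher of 22 (13 adjusted over the list alone, permutation adjusted p = 0.28), a count that moved by over 1.5 times in 18 of the 60 leave-outs and was 6 without NZO 1, 2, 3 or 4. Fatty acid oxidation had 14 higher of 35 (also 14 adjusted over the list alone, permutation adjusted p = 0.0781, 0.037 without NZO 8), among them Vnn1 (2.75 ± 0.36).

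Interferon genes had 37 higher and 1 lower of 41 in NZO (also 37 and 1 adjusted over the list alone, score 0.95, permutation adjusted p = 0.00775). Ifi27 was at 1.35 ± 0.13 (SE) and Mx1, an antiviral GTPase, at 3.48 ± 0.23. MHC class II had 6 of 8 higher (8 adjusted over the list alone, score 1.62, permutation adjusted p = 0.000293). H2-Eb1 was at 3.04 ± 0.23. MHC class I had 13 higher and 5 lower of 19 (also 13 and 5 adjusted over the list alone, 3 lower without NZO 6 or NZO 7, permutation adjusted p = 0.557). NRF2 targets had 9 of 13 higher (also 9 adjusted over the list alone, score 0.65, permutation adjusted p = 0.000293). Ephx1, the microsomal epoxide hydrolase, was at 1.35 ± 0.16 and Txnrd1 at 0.61 ± 0.08. Red cell transcripts had 8 of 8 higher (also 8 adjusted over the list alone, score 1.42, permutation adjusted p = 0.00132, and 1.06 and 0.00469 without the alpha globins). Slc4a1 was at 2.14 ± 0.27 and Hbb-bs at 0.68 ± 0.16. Bile acid genes had 2 higher and 11 lower of 24 (4 and 11 adjusted over the list alone, score -0.44, permutation adjusted p = 0.00538). Cyp7b1 was at -3.09 ± 0.67 and the export pump Abcb11 at -1.21 ± 0.19. Without NZO 8, 5 bile acid genes were higher and 8 lower, and without NZO 5, 0 were higher. Xenobiotic P450s had 6 higher and 12 lower of 34 (6 and 13 adjusted over the list alone, permutation adjusted p = 0.943). Cyp2e1 was at -0.95 ± 0.17. The urea cycle list had 1 higher and 6 lower of 20 (also 1 and 6 adjusted over the list alone, permutation adjusted p = 0.0734, 0.0451 without Cast 5 and 0.242 with 4 lower without NZO 8). Cps1, its first enzyme, was at -0.77 ± 0.15. Oxidative phosphorylation had 1 higher and 19 lower of 39 (also 1 and 19 adjusted over the list alone, permutation adjusted p = 0.0945). Cox5a was at -0.30 ± 0.06.

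Neutrophil, macrophage and cell cycle genes were higher in NZO to a degree that depended on NZO 8, in which Ngp, a neutrophil granule protein gene, was at 566 CPM. All 6 neutrophil markers were higher (also 6 adjusted over the list alone, score 1.94, permutation adjusted p = 0.00486), 4 of them without NZO 8 (score 0.98, permutation adjusted p = 0.0322). S100a9 was at a log2 fold change of 7.34 ± 0.52 (SE) and at 1.61 without NZO 8, Ltf at 8.76 and 1.66, Ngp at 9.13 and 1.75, and Mmp9 at 4.38 and 1.13. S100a8, higher in 6 of 8 libraries, was at 1.11 without NZO 8 (adjusted p = 0.0525). Cell cycle genes had 16 higher of 17 (also 16 adjusted over the list alone, score 1.33, permutation adjusted p = 0.000293) and 14 without NZO 8 (score 1.06). Mki67 was at 3.11 ± 0.24 and 2.35, and Top2a at 2.54 ± 0.27 and 1.42. Kupffer cell markers had 15 of 18 higher (also 15 adjusted over the list alone, score 0.99, permutation adjusted p = 0.00538), 14 without NZO 8. Adgre1, the F4/80 gene, was at 1.41 ± 0.20. Lipid-associated macrophage markers had 11 of 12 higher (also 11 adjusted over the list alone, score 1.12, permutation adjusted p = 0.0028), 10 without NZO 8. Spp1, osteopontin, was at 1.25 ± 0.17 and Ccr2 at 2.50 ± 0.27 and 1.41 without NZO 8. Lymphocyte markers had 18 higher and 1 lower of 22 (also 18 and 1 adjusted over the list alone, permutation adjusted p = 0.0656) and 11 and 2 without NZO 8. Acute phase genes were not called as a list, and their direction rested on NZO 8. They had 12 higher and 2 lower of 29 (also 12 and 2 adjusted over the list alone, permutation adjusted p = 0.49) and 2 and 7 without NZO 8. Saa1 was at 3.40 and at 0.22 without NZO 8, and Lcn2 at 2.90 and at -0.71.

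Of the 7455 genes called in NZO, 4309 were higher and 3146 lower. A4gnt, a glycosyltransferase gene (ENSMUSG00000037953, chromosome 9, 99612502 to 99622367), was at 71.9 ± 21.7 CPM (SD, n = 8) against 0.00852 CPM in Cast to 13 CPM in PWK. Cyp39a1, an oxysterol hydroxylase (ENSMUSG00000023963, chromosome 17, 43667425 to 43751431), was lower by 5.03 ± 0.86 (SE, adjusted p = 2.35e-06), and Igfbp2 was lower by 3.24 ± 0.23 (adjusted p = 1.92e-17). Pnpla3 was higher in 6 of 8 libraries (3.88 ± 0.46, adjusted p = 3.99e-10). Camera called the lipid droplet, P450, interferon, class II, class I, urea cycle, NRF2, oxidative phosphorylation, cell cycle, Kupffer, lipid-associated macrophage, lymphocyte, neutrophil and red cell lists, with an adjusted p of 0.9995 with an estimated correlation. With the Xist covariate, the camera calls of the P450 (adjusted p = 0.0899) and neutrophil lists (0.0549) ended. It then called fatty acid oxidation (0.0359), male-biased genes (0.000487) and urinary proteins (0.00243), each with an adjusted p of 0.9995 with an estimated correlation and no covariate.

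PWK had lower levels of lipid droplet and fatty acid oxidation genes and higher levels of a few genes nearly silent elsewhere. Of 19 lipid droplet genes, 2 were higher and 11 lower (2 and 12 adjusted over the list alone, score -0.95, permutation adjusted p = 0.00384). Pparg was at 0.230 ± 0.183 CPM (SD, n = 8, log2 fold change -3.84 ± 0.43 (SE)), Vldlr at -3.70 ± 0.68 and Plin2 at -0.57 ± 0.19. Fatty acid oxidation had 2 higher and 16 lower of 35 (also 2 and 16 adjusted over the list alone, score -0.73, permutation adjusted p = 0.0306). Acaa1a was at -0.92 ± 0.13, the carnitine palmitoyltransferase gene Cpt2 at -0.56 ± 0.09 and Cyp4a14 at 4.45 ± 3.72 CPM against 73.4 CPM in NOD to 863 CPM in AJ. The NOD mean of Cyp4a14 was 43.5 CPM without NOD 4, which was at 283 CPM. Miox, the inositol oxygenase (ENSMUSG00000022613, chromosome 15, 89334398 to 89337015), was at 36.9 ± 3.51 CPM against at most 0.251 CPM. E2f7, an atypical cell cycle repressor (ENSMUSG00000020185, chromosome 10, 110745439 to 110787384), was at 119 ± 22.1 CPM against at most 8.82 CPM (6.38 ± 0.20, adjusted p = 7.3e-34). Trim12c (ENSMUSG00000057143, chromosome 7, 104338754 to 104353362) was at 0.0581 ± 0.0836 CPM (0.0373 CPM without PWK 9) against 2.83 to 20.4 CPM (-7.35 ± 0.26, adjusted p = 7.37e-32, and -7.99 without PWK 9).

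Of the 7302 genes called in PWK, 3634 were higher and 3668 lower. The interferon list had 24 higher and 4 lower of 41 (also 24 and 4 adjusted over the list alone, permutation adjusted p = 0.275). Xaf1 was at 2.14 ± 0.17 (SE) and Mx2 at 4.16 ± 0.22. MHC class I had 1 higher and 13 lower of 19 (also 1 and 13 adjusted over the list alone, score -0.62, permutation adjusted p = 0.0448). H2-K1 was at -1.32 ± 0.11. NRF2 targets had 7 lower of 13 (also 7 adjusted over the list alone, score -0.40, permutation adjusted p = 0.0102). Gclm, a glutathione synthesis gene, was at -0.54 ± 0.07 and Hmox1 at -0.93 ± 0.17. Sinusoidal endothelial markers had 6 higher and 1 lower of 16 (also 6 and 1 adjusted over the list alone, score 0.27, permutation adjusted p = 0.00574). Lyve1 was at 1.90 ± 0.15 and Kdr at 0.52 ± 0.08. Cholangiocyte markers had 1 higher and 4 lower of 9 (also 1 and 4 adjusted over the list alone, score -0.40, permutation adjusted p = 0.0028). Krt19 was at -0.94 ± 0.21 and Epcam at -0.91 ± 0.21. Neutrophil markers had 3 lower of 6 (also 3 adjusted over the list alone, permutation adjusted p = 0.0831, 0.00181 without NZO 8). Cholesterol synthesis had 12 higher of 22 (13 adjusted over the list alone, permutation adjusted p = 0.269), 6 without PWK 6 or PWK 7. Camera called fatty acid oxidation, interferon, class I and NRF2 lists, with an adjusted p of 0.9995 with an estimated correlation, and with the Xist covariate also male-biased genes (adjusted p = 0.0223, and 0.9995 with an estimated correlation and no covariate). Pnpla3 was higher in 7 of 8 libraries (3.04 ± 0.47, adjusted p = 2.81e-07).

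WSB had higher major urinary protein, complement and respiratory chain transcripts and lower class II, macrophage and lymphocyte transcripts. Of 19 major urinary protein genes, 13 were higher and 1 lower (also 13 and 1 adjusted over the list alone, score 2.45, permutation adjusted p = 0.0224). Mup13 (ENSMUSG00000089873, chromosome 4, 61224307 to 61228286) was at 2110 ± 1650 CPM (SD, n = 8) against at most 10.3 CPM, although assignment within this family is uncertain. Complement and coagulation had 17 higher and 3 lower of 27 (also 17 and 3 adjusted over the list alone, score 0.35, permutation adjusted p = 0.00986). Hc was at 1.22 ± 0.11 (SE) and Serpinc1, antithrombin, at 0.54 ± 0.10. Oxidative phosphorylation had 22 higher and 0 lower of 39 (also 22 and 0 adjusted over the list alone, score 0.16, permutation adjusted p = 0.0429). Atp5g1 was at 0.36 ± 0.06 and Ndufb5 at 0.28 ± 0.05. MHC class II had 1 higher and 7 lower of 8 (also 1 and 7 adjusted over the list alone, score -1.29, permutation adjusted p = 0.00616). H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34305877 to 34316199) was at 0.332 ± 0.225 CPM against 1.01 to 60.2 CPM and Cd74 at -1.11 ± 0.26.

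Of the 7277 genes called in WSB, 3659 were higher and 3618 lower. Kupffer cell markers had 9 lower of 18 (12 adjusted over the list alone, score -0.77, permutation adjusted p = 0.037). Folr2 was at -5.10 ± 0.33 (SE) and Timd4 at -1.40 ± 0.25. Lymphocyte markers had 1 higher and 14 lower of 22 (also 1 and 14 adjusted over the list alone, score -0.97, permutation adjusted p = 0.00656). Ptprc was at -1.09 ± 0.23. The interferon list had 3 higher and 27 lower of 41 (also 3 and 27 adjusted over the list alone, permutation adjusted p = 0.0602). Tgtp1 was at -5.72 ± 0.70 (-6.48 without WSB 9) and Gbp3 at -2.64 ± 0.35. Cholesterol synthesis had 1 higher and 12 lower of 22 (1 and 15 adjusted over the list alone, permutation adjusted p = 0.209). Mvd was at -1.55 ± 0.39. Apolipoproteins had 11 higher and 2 lower of 23 (14 and 2 adjusted over the list alone, permutation adjusted p = 0.0973). Apoc3 was at 0.55 ± 0.09. In WSB, camera called the urinary protein, complement, oxidative phosphorylation, Kupffer, lymphocyte, interferon, cholesterol and apolipoprotein lists, with an adjusted p of 0.9995 with an estimated correlation, and with the Xist covariate also class II (adjusted p = 0.0463, and 0.9995 with an estimated correlation and no covariate). Nxpe2 (ENSMUSG00000032028, chromosome 9, 48318006 to 48353454) was at 0.119 ± 0.101 CPM (SD, n = 8) against 13 to 28.4 CPM (-7.36 ± 0.48, adjusted p = 3.11e-19). Sult1e1 was higher by 6.24 ± 0.29 (adjusted p = 6.19e-26). The desaturase gene Scd1 was lower in 7 of 8 libraries (-1.24 ± 0.37, adjusted p = 0.00489).

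Genes with known differences between mouse strains differed among these strains too. Nnt, the mitochondrial transhydrogenase (ENSMUSG00000025453, chromosome 13, 119335448 to 119408997), was lowest in B6, at 59.7 ± 4.48 CPM (SD, n = 7), followed by Cast at 68.3 ± 34.3 CPM, against 119 to 164 CPM in the other strains. Glo1, glyoxalase 1 (ENSMUSG00000024026, chromosome 17, 30592866 to 30612659), was at 860 ± 105 CPM in AJ and 692 ± 117 CPM in strain-129 against 252 to 370 CPM. Hc (ENSMUSG00000026874, chromosome 2, 34983331 to 35061438) was at 281 ± 23.4 CPM in AJ and 280 ± 44.9 CPM in NOD against 890 to 1600 CPM. Alad, an enzyme of heme synthesis (ENSMUSG00000028393, chromosome 4, 62509169 to 62519918), ranged from 45.4 ± 20.5 CPM in Cast to 214 ± 16.2 CPM in AJ. Mx1 (ENSMUSG00000000386, chromosome 16, 97447035 to 97462907) was at 11.3 ± 4.09 CPM in NZO and 5.14 ± 1.71 CPM in PWK against at most 1.75 CPM. Its neighbour Mx2 (ENSMUSG00000023341, chromosome 16, 97535308 to 97560900) was at 73.9 ± 98.7 CPM in Cast and 63.2 ± 20.1 CPM in PWK but 0.0193 ± 0.0233 CPM in NZO. The Cast mean of Mx2 was 37.9 CPM without Cast 5, which was at 290.3 CPM. Pctp, a phosphatidylcholine transfer protein (ENSMUSG00000020553, chromosome 11, 89982665 to 90002894), was lowest in NOD, at 11.6 ± 8.81 CPM against 31.5 to 122 CPM. H2-Ea-ps, a class II gene (ENSMUSG00000036322, chromosome 17, 34342933 to 34344643), had 3 reads in B6, 4 in strain-129, 7 in NOD and 8 in PWK, and was at 4.67 ± 2.77 CPM in Cast to 25 ± 14 CPM in NZO. Apoa2 was at 1470 ± 479 CPM in Cast against 2190 to 3290 CPM, and Ide, an insulin-degrading protease, at 89.7 to 117 CPM over the strains.

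**Figure D4:**
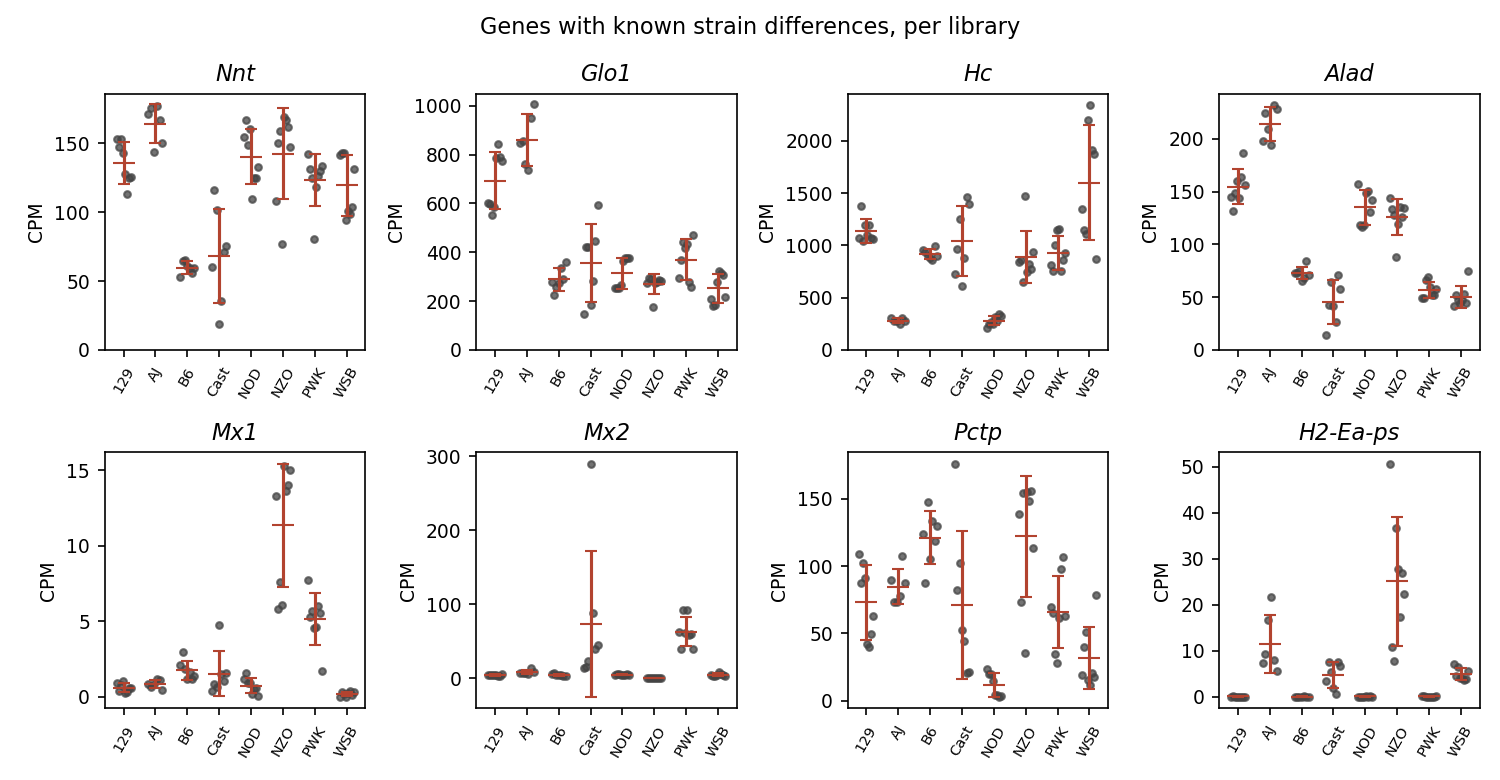
Panels show the CPM of each library by strain for Nnt, Glo1, Hc, Alad, Mx1, Mx2, Pctp and H2-Ea-ps, with the mean and SD of each strain. Hc lies at 281 CPM in AJ and 280 CPM in NOD, below every other strain mean.

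The scores of 7 lists were called in 0 of the 8 strains: acute phase, unfolded protein response, immediate early, male-biased, female-biased, xenobiotic P450 and urea cycle genes. Every strain held libraries of high and of low Xist. The female-biased score had a SD within the strain of 3.22 in strain-129, 3.12 in B6 and 2.33 in AJ. A missing score call of the sex-biased lists therefore says little. With the Xist covariate, camera called male-biased genes in NZO and PWK and female-biased genes in strain-129. Members of these lists still differed. In Cast, 17 acute phase genes were higher and 5 lower of 29 (18 and 6 adjusted over the list alone), with 6 higher without Cast 6. Saa4 was at -2.02 ± 0.32 (SE). The list had a median of 0.69, a mean of 0.62 and a score of -0.02 (permutation adjusted p = 0.98). The unfolded protein response had 13 higher of 19 in Cast (also 13 adjusted over the list alone, permutation adjusted p = 0.181), and 4 without Cast 5. Male-biased genes had 9 higher and 1 lower of 17 in WSB (10 and 1 adjusted over the list alone, permutation adjusted p = 0.387). Selenbp2 was at 3.89 ± 0.66. Urea cycle and amino acid breakdown had 11 higher and 4 lower of 20 in WSB (12 and 4 adjusted over the list alone, permutation adjusted p = 0.289), with 7 higher without WSB 9 and 2 lower without WSB 5. Asl was at 0.60 ± 0.16 but Oat at -1.29 ± 0.24. In Cast, the score of that list had a permutation adjusted p of 0.105, and of 0.00508 without Cast 5. In NZO, the acute phase median was 0.39 and the mean 0.78, but camera gave a downward direction (adjusted p = 0.969), and the score of 0.29 became -0.06 without NZO 8. The adipose and pancreatic acinar lists had 1 tested member each and were not tested.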

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

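The tests of the NZO 8, alpha globin and strong-call patterns were chosen only after the results were seen, while the comparison of each library with the others of its strain followed a fixed rule. That rule, Dixon's test at the 95% level, was run on 386 groups of values (a gene or a library measure in 1 strain). It found a library far from the others in 55 of them. For independent groups of normally distributed values, chance flags about 1 in 20. These groups share libraries, mix high- and low-Xist libraries and include genes named for their fold changes in the same libraries. The 55 are thus not to be compared with that rate. NZO 8 was the library concerned in 27 of the 55. Some of these genes were named in part because of NZO 8, such as Ngp, whose NZO mean was 71.1 CPM and 0.417 CPM without it.

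In NZO 8, transcripts of neutrophils and other leukocytes lay far above the other 7 NZO libraries: Ngp was at 566 CPM, Ltf at 423 CPM, S100a9 at 714 CPM, S100a8 at 526 CPM, Mmp9 at 56.5 CPM, Lyz2 at 731 CPM, Ccr2 at 34.2 CPM, Ptprc at 95.2 CPM and Nkg7 at 4.93 CPM. The cell cycle genes Mki67 (97.7 CPM), Top2a (42.6 CPM), Ccna2 (9.64 CPM) and Ccnb2 (4.87 CPM), the acute phase gene Lcn2 (1140 CPM) and the low-level gene Btnl9 (0.411 CPM) were also above the others. Lipid genes were below them, with Scd1 at 404 CPM, Mogat1 at 1.45 CPM, Fitm1 at 2.97 CPM, Vldlr at 4.84 CPM and Cyp4a14 at 36.4 CPM. Below the others were also Ifi27 (29.1 CPM), the respiratory chain genes Cox5a (50.4 CPM), Ndufb5 (32.0 CPM), Atp5h (75 CPM) and Cox4i1 (156 CPM), and A4gnt (25.7 CPM) and Hist2h2aa2 (11.8 CPM). Beyond these, Saa1 was at 7370 CPM against at most 442 CPM in the other NZO libraries, and Alb at 13100 CPM against 30600 to 79600 CPM.

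The tables argue against several technical sources of the NZO 8 pattern. A library of another strain under the wrong label is argued against by a correlation of 0.9475 with the nearest NZO library, above the 0.9239 with the nearest library of another strain, B6 6. For blood left in the tissue, only red cell RNA was examined. Hbb-bs, a beta globin, was at 113 CPM, within the 110 to 377 CPM of the other NZO libraries. This argues against more blood of the usual makeup but cannot speak on blood rich in leukocytes. Low depth is argued against by a total of 29.8 M reads, within the 22.4 to 69.2 M of the other NZO libraries. Blood rich in leukocytes and an inflamed liver in this mouse stay open as hypotheses. The labels give nothing to test them with, so no biological explanation was tested.

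Hba-a1, an alpha globin gene, averaged 0.116 to 0.543 CPM in strain-129, AJ, B6 and Cast against 46.0 to 170 CPM in NOD, NZO, PWK and WSB. Less red cell RNA in the first 4 strains is argued against by Hbb-bs, whose means spanned 1.46 on the log2 scale over the strains, against 10.52 for Hba-a1. Reads shared with the near-identical copy Hba-a2 are a candidate explanation: the log2 ratio of the summed Hba-a1 and Hba-a2 to Hbb-bs spanned 0.43 over the strains, against 9.47 for Hba-a1 alone. Hist2h2aa1 and Hist2h2aa2 had the same kind of pattern, with Hist2h2aa2 at 49.3 CPM and Hist2h2aa1 at 4.35 CPM in NOD against 0.0710 and 40.8 CPM in strain-129 (Hist2h2aa2 was at 0.0325 CPM without library 2 of strain-129, which was at 0.341 CPM). Whether a strain differs in the true output of either copy stays open.

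Of the calls of at least 4-fold, 62.15% were lower in Cast and 51.18% in PWK. In the other 6 strains the share ranged from 25.06% (NOD) to 57.35% (AJ), with a mean of 41.34% and a SD of 15.57%. WSB, among these 6, was at 57.29%, above PWK. Loss of reads at alleles that differ from the reference sequence is a candidate explanation for part of the lower calls in Cast and PWK. It cannot be told apart from lower expression here, since both shares lay within 2 SD of that mean and reads were not aligned here. Lower expression in these strains stays open as untested. Loss of reads at such alleles could also move the counts and scores of lists. The MHC class I genes, higher in B6 and lower in Cast and PWK, are an example for which it was not tested.

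Among single libraries of the other strains, library 2 of strain-129 was high in Akr1c18 (0.298 CPM), library 3 of strain-129 low in Lss (13.8 CPM), and library 8 of strain-129 low in Apoa4 (2010 CPM). AJ 8 was low in Cyp2b13 (7.43 CPM) and Cyp4a14 (355 CPM). B6 8 was low in H2-T22 (71.1 CPM), B6 6 high in H2-D1 (571 CPM) and B6 2 high in Atp5g1 (103 CPM). Cast 1 was high in Wfdc17 (0.0333 CPM), Cast 3 in Cyp2b13 (0.119 CPM) and Cast 2 in Cd3g (0.0965 CPM), all near 0. NOD 5 held most of the few H2-Ea-ps reads of its strain (0.208 CPM). NZO 6 was high in Cps1 (5650 CPM) and Hpd (1950 CPM). PWK 5 was high in Cpt1a (478 CPM) and Gbp6 (0.110 CPM, with 0 in the other PWK libraries) and low in H2-Q7 (3.76 CPM), and PWK 9 was low in Xaf1 (9.0 CPM). WSB 9 was low in Nuggc (0.207 CPM) and high in Cyp3a59 (1.18 CPM), Tgtp1 (0.443 CPM) and Pparg (2.98 CPM), and WSB 8 was low in Stard4 (24.1 CPM).

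Library measures also stood apart. NZO 3 had 69.1699 M reads, where the next NZO library had 38.17 M. AJ 6 had 17396 genes above 0 against 17799 in the next AJ library. Mitochondrial genes took 5.4043% of the reads in B6 2, low for its strain, and 7.5093% in WSB 5, high for its strain. The TMM factor of Cast 5 was 1.1917 against 1.0602 for the next Cast library.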

How the results depend on the processing

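Leaving out libraries, the list score and its form without alpha globins were tests chosen only after the results were seen, and the other alternatives were planned. Every count of called genes stayed within 1.5 times its value. Over the planned ones the count among the 8 strains ranged from 11647 to 15635, and those of single strains from 3396 to 4459 (strain-129), 3316 to 4236 (AJ), 4400 to 5892 (B6), 8009 to 10160 (Cast), 3844 to 5060 (NOD), 6078 to 7960 (NZO), 6024 to 7693 (PWK) and 6117 to 7588 (WSB). The lowest counts came from the stricter filter, which tested fewer genes. The highest came from the Xist covariate, except among the 8 strains and in Cast, where they came from testing without a filter. Leaving out 1 library gave 14397 to 14593 genes among the 8 strains, 3379 to 4137 in strain-129, 3187 to 4089 in AJ, 4790 to 5828 in B6, 8825 to 9809 in Cast, 4027 to 4720 in NOD, 6864 to 7667 in NZO, 6779 to 7481 in PWK and 6649 to 7507 in WSB. None of the 252 alternative counts between pairs of strains moved by over 1.5 times.

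Counts of calls of at least 2-fold moved by over 1.5 times in 16 of 72 alternatives, all lower, and the cause was not tested apart from the smaller number of genes under the stricter filter. Under that filter they were 556 (strain-129), 651 (AJ), 766 (B6), 1722 (Cast), 693 (NOD), 1126 (NZO), 1193 (PWK) and 974 (WSB), and with limma on the deposited log2-scale values 281, 331, 382, 1144, 321, 532, 786 and 537 in the same order. DESeq2 size factors moved the median fold change of all genes by at most 0.0127 on the log2 scale.

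Camera called 58 list tests. An estimated correlation gave 0 calls, with 8 tests at an unadjusted p under 0.05, since correlations of the called lists were estimated at 0.146 to 0.83 in place of 0.01. The list score called 49, of which 34 were also camera calls, and also 49 with the red cell list without Hba-a1 or without both alpha globins. Other alternatives gave 46 (stricter filter) to 62 (Xist covariate) camera calls, and leaving out 1 library gave 52 (without B6 6) to 64 (without NZO 6). The number of the 58 calls that ended was 12 under the stricter filter, 8 on the log2-scale values, 5 without NZO 8, 4 with the Xist covariate and 3 without Cast 5. Of the 58, 19 ended without at least 1 of the 60 libraries. Counts of called list members, most often counts of 1 to 3, could move by over 1.5 times without a single library.

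Of 358 calls of a named gene in a strain, 41 ended in limma-voom, 18 with limma on the log2-scale values, 2 of 353 in DESeq2, 2 each without a filter, with the Xist covariate, with the library number and without Cast 5, and none with DESeq2 size factors or, of 339 kept, under the stricter filter. Without NZO 8, 4 ended and Lcn2 in NZO reversed to -0.71, against at most 2.89, without Cast 5. The causes were not tested. The share of variance between strains, as a median over genes 49.28%, was 48.84% with a prior count of 0.5, 49.21% on the log2-scale values and 51.02% under the stricter filter.

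Sample numbers were not treated as pairs, since not every pair correlated: 181 pairs of libraries with the same number had correlations of within-strain deviations with a median of 0.201 (-0.0699 for different numbers) and a lowest value of -0.429, with 72.4% over 0.1. The number carried shared structure, as 28 of the 30 libraries numbered 1 to 4 and 3 of the other 30 had high Xist, and 13 of the 60 libraries correlated best with one of their own number. With the number as a block the counts were 14416 among the strains, 3865 (strain-129), 3913 (AJ), 5411 (B6), 9563 (Cast), 4693 (NOD), 7569 (NZO), 7400 (PWK) and 7204 (WSB), 8 of the 358 named calls and 3 of the 58 list calls ended, and 62 list tests were called. Depth limits genes under about 0.1 CPM, which a strain covered with a few reads per library.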

Other observations

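The tests below, and the limits of 0.5 and 5 CPM, were chosen only after the results were seen, except the clock test, whose prediction was written beforehand. Some genes were nearly silent in a single strain or active in a single strain (strain mean under 0.5 CPM against at least 5 CPM in each other strain, or the reverse). In Cast, 6 genes were low in this way and 7 high. The low ones included Hao2 (0.127 CPM against 17.6 to 70.8 CPM), a peroxisomal hydroxyacid oxidase, and the high ones included the taste receptor gene Tas1r1 (40.6 CPM against at most 0.134 CPM). In PWK, 2 were low and 9 high, among them Ubash3a (25.1 CPM against at most 0.277 CPM), a regulator of T cell signalling, Xrra1 (9.95 CPM) and Lrrtm3 (6.16 CPM).

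In NZO, 5 genes were high in this way, and each of them missed the limit without NZO 8. A2m, the protease inhibitor alpha-2-macroglobulin, averaged 26.4 CPM in NZO but 0.137 CPM without NZO 8, which was at 210 CPM, and Igdcc4 11.1 CPM but 0.328 CPM without it. The other 3, Ngp, Ltf and Prtn3, are neutrophil genes, at 0.417, 0.385 and 1.06 CPM without it. In strain-129, Gdpd3 (9.58 CPM against at most 0.265 CPM) and Wdr72 (7.34 CPM against at most 0.0679 CPM) were high. Dysf, which encodes the membrane repair protein dysferlin, was low in AJ (0.414 CPM against 5.07 to 8.71 CPM). Nxpe2 (0.119 CPM against 13 to 28.4 CPM) and Pla2g16 (0.424 CPM against 5.06 to 20.3 CPM) were low in WSB. No gene met either limit in B6 or NOD. Dysf missed the limit in 4 of the 60 leave-outs of 1 library, Pla2g16 in 4, and in Cast Hamp2 in 5, Gm8941 in 3, Gm10182 and Patl2 in 2 each and Hspd1-ps4 in 1.

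Xist, the RNA of the inactive X chromosome, was at 645.64 to 1421.5 CPM in 31 libraries and at most 8.90 CPM in the other 29. The Y-linked gene Ddx3y was at most 1.76 CPM in those 31 libraries and at least 52.3 CPM in those 29. The high-Xist libraries numbered 4 of 8 in strain-129, NOD, NZO, PWK and WSB, 4 of 6 in AJ, 4 of 7 in B6 and 3 of 7 in Cast. The labels give no sex, and high- and low-Xist libraries were not compared, apart from the use of Xist as a covariate. Strain was the only factor of the main model, so the mean and SD of each strain pool high- and low-Xist libraries. In WSB, for example, urinary protein genes took 0.37 to 2.62% of reads in high-Xist libraries and 6.90 to 8.05% in low-Xist ones.

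Clock genes varied widely within strains. Dbp, an output gene of the clock, had a SD of 2.05 around the strain means on the log2 scale over the 60 libraries, and Arntl, which encodes a core activator, a SD of 0.83. The hypothesis that libraries differ in the time of day of collection predicts opposite deviations of both genes, since they peak at opposite times. Pearson's r of the deviations was -0.86 and Spearman's rho -0.84, each with a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give, for the 1 relation computed. Without Cast 7 and B6 7, the libraries farthest from the median of Dbp, r was -0.87. It was below 0 in 8 of 8 strains, from -0.99 in PWK to -0.60 in NOD and -0.09 in NZO, where Dbp spanned 2.18 to 21.9 CPM. These values are consistent with collection at different times, which the labels do not give, and a clock set differently in some mice could give the same relation. In NOD, Dbp lay at 0.181 to 1.46 CPM and Arntl at 29.6 to 39.1 CPM, so the lower clock list there cannot be separated from collection time. The range of Dbp differed among other strains too, such as 0.637 to 11.7 CPM in WSB and 0.438 to 95.1 CPM in B6. Levels of other genes that follow the time of day, in any list above, could differ between strains for the same reason, which was not tested.

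For each count of called genes, 1 of 40 splits of the libraries into groups of the same sizes, the real one, gave a count as large. A share of 1 of 40 is the smallest that this number of splits can give. It argues against chance for the count among the 8 strains without excluding it. All strain labels were shuffled at once, so differences between the other strains widened the spread in those splits. For a single strain or a pair of strains, the splits therefore cannot decide. The highest count in the other splits was 402 against 14518 among the 8 strains, 448 against 3979 for strain-129, 654 against 3893 for AJ, 353 against 5506 for B6, 558 against 9630 for Cast, 303 against 4580 for NOD, 371 against 7455 for NZO, 480 against 7302 for PWK and 2103 against 7277 for WSB. Between pairs of strains, the lowest real count was 2327 and the highest of any pair in another split was 1662. The number of list tests called by camera was different: 38 of 40 splits gave at least the 58 calls of the real one, with a highest of 104, so chance cannot be excluded for that number.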
